A study of Arabidopsis thaliana with 18 samples.

How the data were processed

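The data are the deposited gene table of the authors, in counts per gene for 18 libraries, and a deposited sequencing report that lists reads per library. Per the submitters' processing notes CASAVA 1.4, FastQC, HISAT2, HTSeq and edgeR were used upstream; the genome build is not given in the sources used here, and neither is the strandedness of the kit. The name of the deposited count table speaks of normalized counts, but its values behave as raw counts: all are whole numbers, the lowest whole number absent from a library lies between 647 and 1102, library totals are 20839562 to 21871669 or 88.66 to 91.02% of the clean reads, and median-of-ratios size factors span 0.948 to 1.088. The values were therefore analysed as raw counts, the case that the design written beforehand assigned to edgeR. Alternatives that apply only to normalized values (other pseudocounts, edgeR on recovered reads) were not run.

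The table has 37037 entries, of which 24653 have a read and 12384 have none; 24500 of those with reads were matched to the reference annotation, which was used only for names and for the length and GC content in a trend check. The most abundant gene, PYK10 (AT3G09260), takes 1.48 to 3.38% of a library. No pair of replicates is a duplicate (chi-square per degree of freedom 2.78 to 31.82).

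Genes were kept with filterByExpr (minimum count 10), which left 19982. Libraries were scaled by TMM (factors 0.953 to 1.063) and fitted with glmQLFit and glmQLFTest of edgeR 4.0.16 in R 4.3.3, a mean per group and all 18 libraries in a single fit; the common biological coefficient of variation is 8.5%. Adjusted p is Benjamini-Hochberg over the tested genes of a comparison, with 0.05 as the threshold. All p-values and adjusted p-values for genes come from edgeR, those for lists from camera in limma 3.58.1 with a preset correlation of 0.01, and again with a correlation estimated per list. CPM is the count divided by the scaled library total, from edgeR. The 3 interactions subtract the response in full phosphate from that in low phosphate.

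The pipeline was tested on simulated data with 50 genes changed at each of 4 sizes. For starvation 80% of 1.5-fold, 96% of 2-fold and 100% of 4-fold changes were recovered, with 10 other genes called of 19855. In the isomer comparison at low phosphate 68% of 1.5-fold and 92% of 2-fold changes were recovered, with 5 other genes of 19908. For the isomer-by-phosphate interaction the shares were 46% and 92%, with 6 other genes of 19894, so changes under 1.5-fold are often missed in such data. At 1.25-fold only 20% were recovered in the isomer comparison and 2% in that interaction. Far fewer genes change in the simulated data than are called for starvation (8925) or for that interaction (3666). The Benjamini-Hochberg adjustment depends on the share of changed genes. Neither the shares recovered nor the numbers of other genes called therefore carry over to these comparisons. The simulated libraries also have the same spread per gene in all groups. In the data the replicates of low-phosphate cis-zeatin and trans-zeatin differ more (chi-square per degree of freedom up to 31.82 and 21.39) than those of other groups (up to 12.28). Recovery and false calls in the comparisons that use these groups may therefore be worse than simulated.

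The 25 gene lists (399 genes, all in the table) were written before the data were seen. They cover cytokinin (type-A response regulators, perception, degradation, synthesis), phosphate (uptake, phosphatases, lipid remodelling), iron, nitrate, sulfate, auxin, ethylene, cell division, root hair, lignin, flavonoid, and markers of tissue or handling (photosynthesis, xylem, endodermis, root tip, wounding, heat shock, clock). Genes are named by a rule fixed beforehand: per comparison the 5 largest rises and 5 largest falls among called genes with a mean above the median and non-overlapping replicates (3 and 3 for interactions, without the last condition), the type-A response regulators, and up to 4 members per list with the smallest adjusted p. Nearly identical genes such as the PHT1 transporters beside PHT1;4, RBCS and LHCB1 members, and overlapping genes, are uncertain with 50-nt single-end reads.

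Replicate numbers were tested for pairing by correlating the deviations of libraries from their group means, because the labels do not state it. Only untreated and trans-zeatin libraries in low phosphate pair (r 0.27, 0.30 and 0.17). Other settings tried were DESeq2 1.42.0, median-of-ratios scaling, quantile normalization with limma, no filter, a stricter filter of 50, only the compared groups, robust fitting, a replicate block, a fold threshold of 2, an estimated correlation for lists, and leaving out each library. After seeing the data were added: limma without quantile normalization, removal of the length and GC trend, the sequencing set as a term, and leaving out both low-phosphate zeatin replicates 2. Sequencing sets were inferred from gaps in the number of reads discarded for undetermined bases (81544 to 85178, 22738 to 25354 and 40794 to 58614), and the sources used here do not say whether they are separate runs. The term for the set can be estimated only through the low-phosphate trans-zeatin group, whose replicate 1 is in a different set from replicates 2 and 3. With it the trans-zeatin response in low phosphate rests on replicate 1 alone. The cis-zeatin response there takes on the error of the term. Calls lost with this term can therefore reflect lost replication as well as a set effect.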

Results

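The libraries are poly(A) RNA-seq of Arabidopsis thaliana (Col-0) roots, 3 for each of 6 groups. Plants had 625 µM (full) or 5 µM (low) phosphate for 8 days and were left untreated or given 5 µM trans-zeatin or 5 µM cis-zeatin for 8 h. The zeatin isomers are cytokinins that differ only in the geometry of the side-chain double bond. Each of the 18 libraries has 20839562 to 21871669 counted reads, and 19982 genes had enough reads to be tested. The comparisons ask what low phosphate changes, what each isomer changes at each phosphate level, whether the isomers differ at the same dose and time, and whether any of these responses depends on phosphate. Values are log2 fold changes ± standard error with n = 3 per group, CPM is the count scaled by library size as in edgeR, and a change is named only at an adjusted p under 0.05. Largest rises and falls are those among called genes with expression above the median and replicates that do not overlap. The labels do not say whether replicates are separate cultures, so the p-values measure the spread between samples only.

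The libraries fall into sequencing sets by the number of reads discarded for undetermined bases. The labels name no runs, and the sets may not be separate runs. The untreated and trans-zeatin libraries of full phosphate are in set A, the full-phosphate cis-zeatin and untreated low-phosphate libraries in set B, and the low-phosphate cis-zeatin libraries in set C. Of the low-phosphate trans-zeatin libraries replicate 1 is in set B and replicates 2 and 3 are in set C. The starvation comparison, cis-zeatin in full phosphate and the isomer comparison in full phosphate therefore cross sets completely, so a part played by the set cannot be removed from their values, and the cis-zeatin and isomer interactions include such a comparison. cis-Zeatin in low phosphate also crosses sets, and only the low-phosphate trans-zeatin group links sets B and C. trans-Zeatin in full phosphate was compared within a single set.

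**Figure D1:**
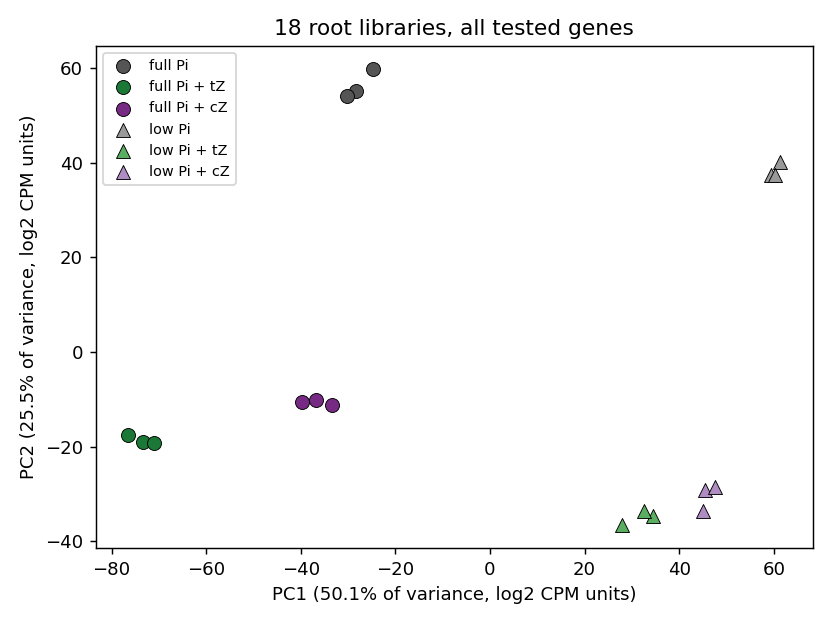
Principal components of log2 CPM of all tested genes, with the first component (50.1% of variance) on the horizontal and the second (25.5%) on the vertical axis; each point is a library, circles are full phosphate, triangles low phosphate, and colours give the treatment. The first component parts the phosphate levels and the second parts zeatin from untreated libraries, and the isomers lie further apart in full than in low phosphate.

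Low phosphate against full phosphate, both untreated, answers what starvation changes in these roots. PECP1 (AT1G17710) rose by 10.51 ± 0.35, IPS1 (AT3G09922) by 9.66 ± 0.25, PS2 (AT1G73010) by 7.03 ± 0.17, OCT1 (AT1G73220) by 6.51 ± 0.24 and SPX1 (AT5G20150) by 6.01 ± 0.15. PECP1 and PS2 encode phosphatases, IPS1 is a non-coding RNA that binds the microRNA miR399, OCT1 is an organic cation transporter, and SPX1 is an SPX-domain repressor of the starvation response. Falls were largest for FRO5 (AT5G23990) (-6.93 ± 0.27), IRT1 (AT4G19690) (-6.75 ± 0.30), AT4G07820 (-5.40 ± 0.19), AGT (AT2G13360) (-4.80 ± 0.14) and COPT2 (AT3G46900) (-4.72 ± 0.22), of which FRO5 and COPT2 belong to copper uptake and IRT1 to iron uptake. Of the genes for phosphate uptake and signalling 16 of 19 rose and 2 fell (median 3.90, adjusted p = 1.99e-05 with an estimated correlation), among them PHT1;4 (AT2G38940) (3.90 ± 0.09, from 48.1 to 719 CPM) and the non-coding AT4 (AT5G03545) (5.35 ± 0.16). Phosphatases and scavenging enzymes had 12 of 14 up and 1 down (median 4.16, adjusted p = 1.99e-05 with an estimated correlation), with PAP17 (AT3G17790) at 5.04 ± 0.14 and PAP12 (AT2G27190) at 2.17 ± 0.08. Membrane lipid remodelling, which replaces phospholipids by lipids without phosphorus, had 13 of 15 genes up (median 3.47, adjusted p = 0.000109 with an estimated correlation): SQD1 (AT4G33030) 3.47 ± 0.08, SQD2 (AT5G01220) 3.58 ± 0.10, NPC4 (AT3G03530) 4.28 ± 0.12 and GDPD1 (AT3G02040) 4.34 ± 0.12.

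Iron acquisition fell in low phosphate, with 16 of 22 genes down and 2 up (median -1.08, adjusted p = 0.00273 with an estimated correlation). The ferric reductase gene FRO2 (AT1G01580) changed by -3.84 ± 0.18, NAS1 (AT5G04950) by -2.57 ± 0.15 and the regulator FIT (AT2G28160) by -1.33 ± 0.08. All 17 root-hair genes rose (adjusted p = 0.0251 with an estimated correlation), including RSL2 (AT4G33880) (2.32 ± 0.13), RHS19 (AT5G67400) (2.82 ± 0.18) and RHS13 (AT4G02270) (2.72 ± 0.18). In the cell-division list 19 of 24 genes rose and none fell (median 0.42), among them CDKB2;2 (AT1G20930) (0.71 ± 0.09) and AUR2 (AT2G25880) (0.60 ± 0.11), but that list passes only with the preset correlation (adjusted p = 0.399 with an estimated correlation). The same holds for lignin synthesis with 11 of 15 up (adjusted p = 0.399 with an estimated correlation; 4CL2 (AT3G21240) 0.81 ± 0.09, PAL1 (AT2G37040) 0.82 ± 0.09). It also holds for nitrate uptake and assimilation with 12 of 20 down (adjusted p = 0.399 with an estimated correlation; BT1 (AT5G63160) -2.48 ± 0.12, NRT1.5 (AT1G32450) -1.73 ± 0.10). Among sulfate genes 7 of 15 fell and 4 rose, and the list is not past the test (adjusted p = 0.0541). APR3 (AT4G21990) changed by -1.32 ± 0.09 and SULTR1;2 (AT1G78000) by -1.24 ± 0.11.

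Cytokinin genes changed in untreated starved roots as well. Of the 10 type-A response regulators, which are early cytokinin-induced genes that dampen the signal, 6 fell and 3 rose (adjusted p = 0.53 with an estimated correlation). ARR7 (AT1G19050) (-1.45 ± 0.11), ARR5 (AT3G48100) (-0.76 ± 0.11) and ARR6 (AT5G62920) (-0.73 ± 0.08) fell, while ARR16 (AT2G40670) (1.08 ± 0.24) and ARR17 (AT3G56380) (2.16 ± 0.52) rose. These rises lie at low levels, ARR16 from 1.56 to 3.3 CPM and ARR17 from 0.198 to 0.898 CPM. CKX4 (AT4G29740), a cytokinin oxidase gene, fell (-2.69 ± 0.12), and so did CYP735A2 (AT1G67110) (-1.41 ± 0.12), whose product makes trans-zeatin-type cytokinins by hydroxylation. IPT3 (AT3G63110), for a step of cytokinin synthesis, changed by -1.17 ± 0.12, and LOG1 (AT2G28305) rose (95% interval 1.02 to 1.58). The synthesis and export list as a whole had 7 genes up and 5 down of 16 and is not past the test (adjusted p = 0.778). Photosynthesis genes, a marker of shoot tissue, had 15 of 16 down (median -1.71, adjusted p = 0.399 with an estimated correlation), as in LHCA4 (AT3G47470) (-1.64 ± 0.16, from 19.6 to 6.29 CPM), and 1 untreated full-phosphate library has more of these reads than its replicates (138 against 79 and 87.3 CPM). Circadian clock genes had 6 of 10 down (adjusted p = 0.308 with an estimated correlation). The root-tip list, a tissue marker, had 3 of 7 genes up and a median of 0.48, close to that of the cell-division list, and is not past the test (adjusted p = 0.452). Xylem (-0.16, adjusted p = 0.251) and wounding (0.18, adjusted p = 0.778) lists are not past it either. With edgeR, 4569 genes rose and 4356 fell, 44.7% of those tested, and 1764 of them changed at least 2-fold.

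**Figure D2:**
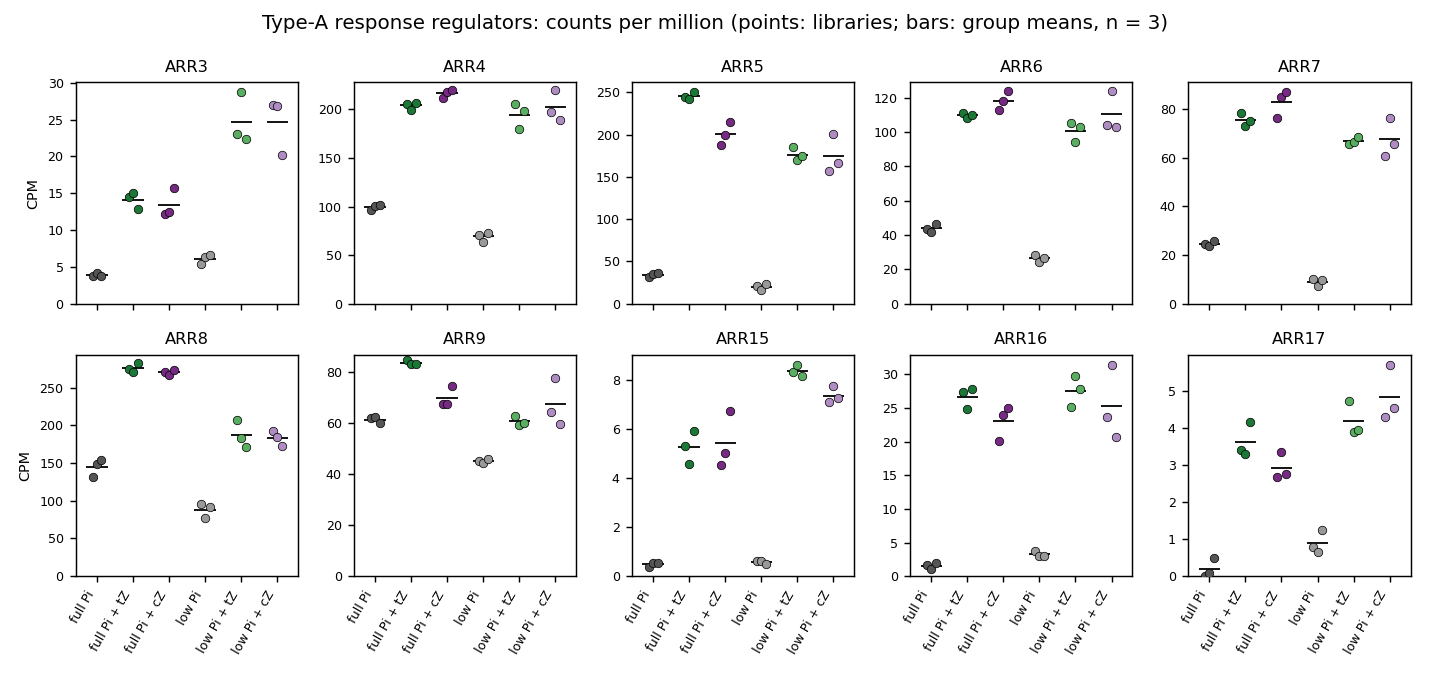
CPM (vertical axis) of the 10 type-A response regulators in the 6 groups; points are libraries and bars group means, n = 3. ARR7 goes from 24.6 to 75.5 CPM with trans-zeatin and to 82.7 with cis-zeatin in full phosphate, and from 8.98 to 66.8 and 67.4 in low phosphate.

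trans-Zeatin in full phosphate, against untreated roots at the same level, shows the response of fed roots. All 10 type-A response regulators rose (median 1.74, adjusted p = 0.00912 with an estimated correlation): ARR16 by 4.09 ± 0.19, ARR15 (AT1G74890) by 3.43 ± 0.21, ARR5 by 2.84 ± 0.11 and, least, ARR9 (AT3G57040) by 0.45 ± 0.08. Of the genes for cytokinin degradation and conjugation 8 of 10 rose (median 1.75, adjusted p = 0.000196 with an estimated correlation), with the oxidase genes CKX5 (AT1G75450) at 2.03 ± 0.08 and CKX4 at 1.77 ± 0.10. In cytokinin synthesis IPT5 (AT5G19040) (-3.67 ± 0.17), IPT7 (AT3G23630) (-6.19 ± 0.35) and IPT3 (-1.51 ± 0.12) fell and CYP735A2 rose (1.99 ± 0.11), and of the list 4 rose and 4 fell. Perception and signalling genes moved both ways, 7 up and 5 down of 20 (adjusted p = 0.752), with the type-B regulator ARR10 (AT4G31920) at -0.75 ± 0.07 and ARR12 (AT2G25180) at 0.58 ± 0.07.

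Nitrate genes fell in 14 of 20 cases (median -0.77, adjusted p = 0.114 with an estimated correlation). The nitrate transporter genes NRT2.1 (AT1G08090) and NRT1.1 (AT1G12110) changed by -4.41 ± 0.29 and -3.93 ± 0.15, and the nitrite reductase gene NIR1 (AT2G15620) by -2.12 ± 0.10. Cell-division genes fell in 22 of 24 cases (median -0.73, adjusted p = 0.25 with an estimated correlation), among them the cyclins CYCB1;1 (AT4G37490) (-1.35 ± 0.13) and CYCB1;3 (AT3G11520) (-0.89 ± 0.10). Iron acquisition had 11 genes down and 6 up of 22 (adjusted p = 0.243 with an estimated correlation), with FRO2 at -3.64 ± 0.18, IRT1 at -3.73 ± 0.23 and FIT at -1.69 ± 0.08. Of the phosphate uptake and signalling genes 11 of 19 fell (median -0.56, adjusted p = 0.492 with an estimated correlation), led by PHT1;4 (-2.67 ± 0.10) and the phosphate exporter genes PHO1;H1 (AT1G68740) (-2.66 ± 0.16) and PHO1 (AT3G23430) (-1.19 ± 0.12), while WRKY75 (AT5G13080) rose (1.08 ± 0.10). Auxin genes moved both ways: the repressor genes IAA17 (AT1G04250) (1.48 ± 0.08) and IAA3 (AT1G04240) (1.81 ± 0.11) and the efflux carrier gene PIN4 (AT2G01420) (1.53 ± 0.12) rose, and GH3.1 (AT2G14960) (-2.68 ± 0.23) and PIN2 (AT5G57090) (-0.97 ± 0.14) fell. Ethylene genes had 9 up and 3 down of 16 (adjusted p = 0.353), with the synthase gene ACS7 (AT4G26200) at 2.27 ± 0.15.

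Largest rises outside these lists are AT4G37220 (5.06 ± 0.23), AT1G58320 (4.07 ± 0.20), PSK2 (AT2G22860) (95% interval 3.62 to 4.37) and SEN1 (AT4G35770) (3.80 ± 0.21), and the largest falls are AGP30 (AT2G33790) (-4.84 ± 0.27) and GSTF14 (AT1G49860) (-4.52 ± 0.16). Photosynthesis genes rose in 11 of 16 cases (median 0.94, adjusted p = 0.679 with an estimated correlation), LHCB4.1 (AT5G01530) by 1.41 ± 0.12, so shoot-type transcripts shift by as much as several root lists do. Endodermis genes moved less as a group (median -0.10), but CASP1 (AT2G36100) fell (-1.05 ± 0.16). Counts past the test with edgeR were 4826 up and 5049 down, and 2078 of these changed at least 2-fold.

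cis-Zeatin in full phosphate raised the same cytokinin markers. Type-A response regulators rose in 9 of 10 cases (median 1.76, adjusted p = 0.00104 with an estimated correlation): ARR16 by 3.88 ± 0.19, ARR15 by 3.48 ± 0.21 and ARR5 by 2.55 ± 0.11. ARR9 is not past the test over all genes (0.18 ± 0.08, adjusted p = 0.0932), and adjusted over the list alone all 10 are. Degradation and conjugation genes rose in 8 of 10 cases (adjusted p = 1.6e-05 with an estimated correlation), with CKX5 at 2.43 ± 0.08 and CKX3 (AT5G56970) at 2.82 ± 0.15. IPT5 (-2.75 ± 0.15) and IPT3 (-1.66 ± 0.13) fell and CYP735A2 rose (2.09 ± 0.11). Nitrate genes fell in 13 of 20 cases (adjusted p = 0.0842 with an estimated correlation; NRT1.1 -1.62 ± 0.13, NIR1 -1.30 ± 0.10), and phosphate uptake and signalling in 11 of 19 (median -1.09, adjusted p = 0.178 with an estimated correlation; PHT1;4 -2.51 ± 0.10, PHO1 -1.18 ± 0.12).

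Root-hair genes rose in 8 of 17 cases with cis-zeatin (median 0.72, adjusted p = 0.457 with an estimated correlation), among them the proline-rich protein gene PRP1 (AT1G54970) (3.15 ± 0.24) and the regulator RSL4 (AT1G27740) (1.01 ± 0.11). Flavonoid genes rose in 5 of 9 cases (adjusted p = 0.457 with an estimated correlation; CHS (AT5G13930) 1.19 ± 0.13, UGT78D2 (AT5G17050) 0.77 ± 0.09). Lignin genes rose in 8 of 15 (adjusted p = 0.496 with an estimated correlation; 4CL1 (AT1G51680) 0.75 ± 0.10) and xylem genes in 7 of 10 (adjusted p = 0.457 with an estimated correlation; XCP1 (AT4G35350) 0.50 ± 0.09). The cyclin gene CYCD3;1 (AT4G34160) rose by 1.05 ± 0.12, whereas the cell-division list is not past the test (median -0.15, adjusted p = 0.398). Iron storage had 4 of 9 genes down (adjusted p = 0.0708), with VTL5 (AT3G25190) at -1.19 ± 0.13. Outside the lists AT2G25150 (3.83 ± 0.20), FLA6 (AT2G20520) (3.40 ± 0.21) and ST4B (AT1G13420) (3.40 ± 0.14) rose most, and AGP30 (-4.90 ± 0.27) and the aquaporin gene TIP2;3 (AT5G47450) (-4.01 ± 0.15) fell most. Photosynthesis genes had a median of -0.22 (adjusted p = 0.556). With edgeR, 2537 genes rose and 2700 fell, 1328 of them at least 2-fold.

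trans-Zeatin in low phosphate lowered phosphate genes that starvation had raised. PHT1;4 changed by -2.14 ± 0.09 (from 719 to 163 CPM), SPX3 (AT2G45130) by -2.90 ± 0.14, PS2 by -2.80 ± 0.13, PECP1 by -3.05 ± 0.19, MGD3 (AT2G11810) by -2.60 ± 0.14 and OCT1, the largest fall, by -5.16 ± 0.21. Phosphate uptake and signalling had 16 of 19 genes down and none up (median -1.80, adjusted p = 0.000804 with an estimated correlation). Lipid remodelling had 14 of 15 down (median -0.80, adjusted p = 0.00583 with an estimated correlation; SQD1 -1.66 ± 0.07, SQD2 -1.88 ± 0.09). Phosphatases had 9 down and 3 up of 14 (median -1.16, adjusted p = 0.0192 with an estimated correlation; PAP17 -1.80 ± 0.12). PHT1;4 stayed above the full-phosphate level, at 163 CPM against 48.1 in untreated fed roots. All 10 type-A response regulators rose (median 2.11, adjusted p = 0.000479 with an estimated correlation), with ARR15 at 3.86 ± 0.19, ARR5 at 3.12 ± 0.12 and ARR7 at 2.89 ± 0.11. CYP735A2 had the largest rise (3.84 ± 0.12), followed by the trehalose-phosphate phosphatase gene TPPH (AT4G39770) (3.74 ± 0.14), and the degradation list had 9 of 10 genes up (adjusted p = 2.14e-05 with an estimated correlation; CKX4 3.37 ± 0.12). IPT5 fell (-3.18 ± 0.19), and IPT7 went from 2.66 CPM to 0, so no fold is given.

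Other lists moved less in this comparison. Nitrate genes fell in 14 of 20 cases (adjusted p = 0.195 with an estimated correlation; NRT1.1 -1.53 ± 0.13) and cell-division genes in 15 of 24 (adjusted p = 0.592 with an estimated correlation; CDKB2;2 -0.68 ± 0.09), though CYCD3;1 rose (1.05 ± 0.11). Flavonoid genes rose in 5 of 9 (adjusted p = 0.533 with an estimated correlation; CHS 0.85 ± 0.13). Ethylene genes had 11 of 16 up and 4 down (adjusted p = 0.0609 with an estimated correlation), with ACS7 at 1.82 ± 0.15. Auxin response had 11 genes down and 7 up of 24 (adjusted p = 0.405), and auxin transport 6 down and 2 up of 12 (adjusted p = 0.745). IAA17 rose by 1.54 ± 0.08 and PIN4 by 1.43 ± 0.12. Photosynthesis (0.07), endodermis (-0.07), root-tip (-0.10), wounding (-0.18), heat-shock (-0.06) and clock (-0.10) medians are all small, though replicate 2 has lower CASP1 and higher PIN2 than its replicates. With edgeR, 2758 genes rose and 3682 fell, 1518 at least 2-fold. Adding the sequencing set as a term, an alternative chosen after seeing the data, gives 4140 in place of 6440. That fit rests on replicate 1 of the trans-zeatin group, so lost replication can lower the count.

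**Figure D3:**
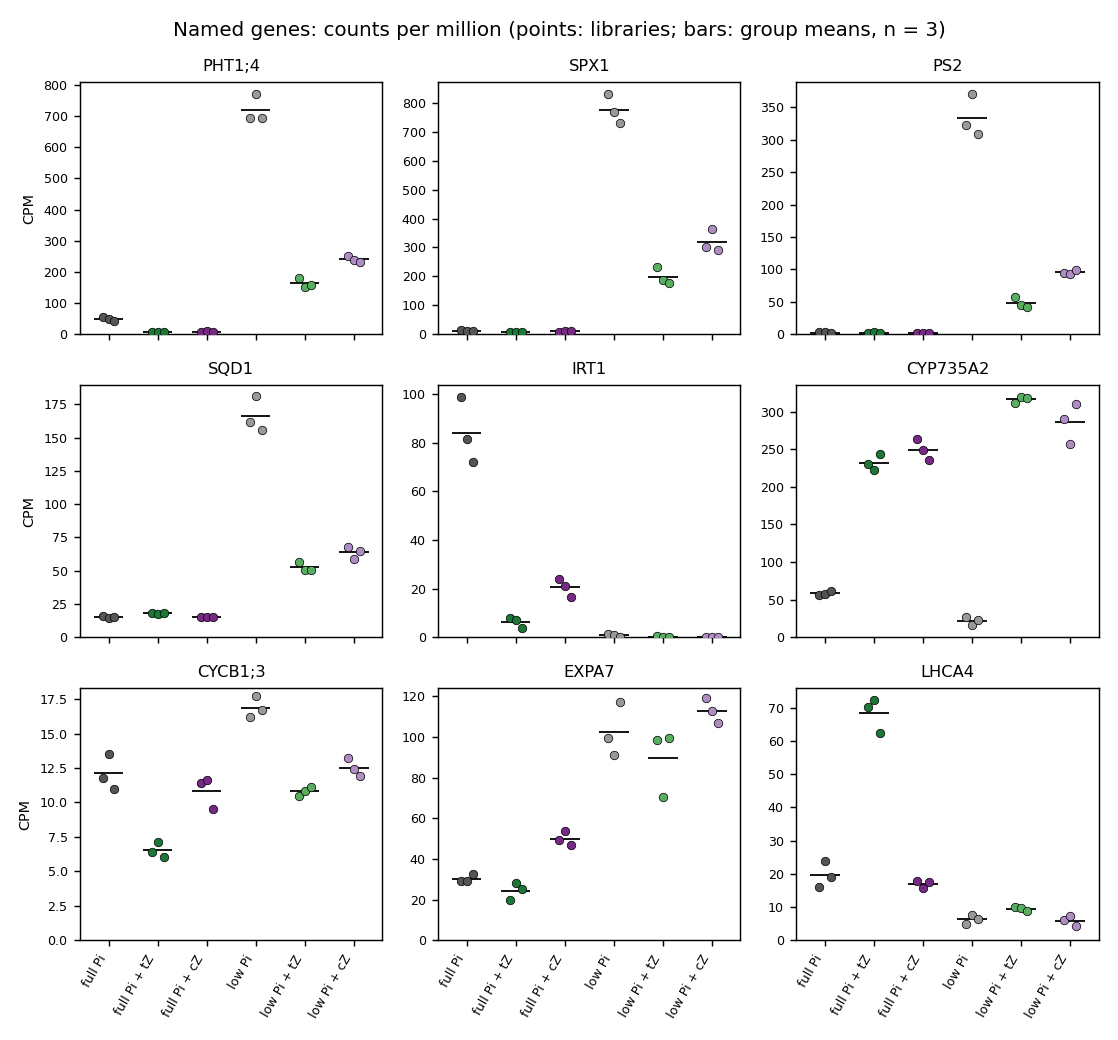
CPM (vertical axis) of 9 genes in the 6 groups; points are libraries and bars group means, n = 3. SPX1 and SQD1 rise in low phosphate and are lower with either zeatin, and IRT1 is near 0 in all low-phosphate groups (84.1 CPM in untreated fed roots).

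cis-Zeatin in low phosphate lowered the same phosphate genes. PHT1;4 changed by -1.58 ± 0.09 (from 719 to 241 CPM), SPX3 by -2.01 ± 0.13, PS2 by -1.81 ± 0.12, MGD3 by -2.24 ± 0.14 and OCT1 by -4.34 ± 0.20. Phosphate uptake and signalling had 16 of 19 down (median -1.20, adjusted p = 0.00582 with an estimated correlation). Lipid remodelling followed in 14 of 15 genes (median -0.83, adjusted p = 0.0098 with an estimated correlation; SQD1 -1.38 ± 0.07, NPC4 -1.31 ± 0.10), and phosphatases had 8 down with 3 up of 14 (median -0.98, adjusted p = 0.124 with an estimated correlation). All 10 type-A response regulators rose (median 2.24, adjusted p = 0.000315 with an estimated correlation; ARR15 3.67 ± 0.19, ARR5 3.11 ± 0.12, ARR7 2.91 ± 0.11), and so did 9 of 10 degradation genes (adjusted p = 2.3e-05 with an estimated correlation; CKX4 3.42 ± 0.12). TPPH (3.80 ± 0.14), AT2G25150 (3.77 ± 0.20), AT5G47980 (3.74 ± 0.14), CYP735A2 (3.69 ± 0.12) and the triterpene synthase gene PEN3 (AT5G36150) (3.52 ± 0.17) are the largest rises, and GSTF14 (-4.66 ± 0.38), TIP2;3 (-3.76 ± 0.16) and TIP2;2 (AT4G17340) (-3.50 ± 0.13) are among the largest falls. IPT7 again went from 2.66 CPM to 0.

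Ethylene genes rose in 9 of 16 cases (adjusted p = 0.0291 with an estimated correlation; ACS7 1.96 ± 0.15) and flavonoid genes in 7 of 9 (adjusted p = 0.0968 with an estimated correlation; CHI (AT3G55120) 1.21 ± 0.12). So did sulfate genes in 11 of 15 (adjusted p = 0.29 with an estimated correlation; APR3 0.87 ± 0.09) and lignin genes in 9 of 15 (adjusted p = 0.392 with an estimated correlation; 4CL1 0.78 ± 0.10). Falls were counted for 12 of 20 nitrate genes (adjusted p = 0.266 with an estimated correlation; NRT1.1 -1.33 ± 0.13) and 14 of 24 cell-division genes (adjusted p = 0.568 with an estimated correlation; CDKB2;2 -0.67 ± 0.09). Iron storage had 5 of 9 genes down (adjusted p = 0.428 with an estimated correlation; VTL5 -1.15 ± 0.14). Heat-shock genes, a marker of handling, rose in 4 of 5 cases (adjusted p = 0.52 with an estimated correlation; HSP101 (AT1G74310) 0.87 ± 0.17), though with the sequencing set as a term only HSP101 of these keeps its call, and xylem genes in 3 of 10 (adjusted p = 0.428 with an estimated correlation). Photosynthesis genes had none past the test (median -0.21). With edgeR, 2613 genes rose and 3620 fell, 1374 at least 2-fold. With the sequencing set as a term 2678 genes are called in place of 6233 and the share up goes from 41.9 to 55%, and replicate 2 of this group lies apart from the other 2 libraries. The term carries its own error into this comparison, so calls lost with it, heat-shock genes included, need not be set effects.

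**Figure D4:**
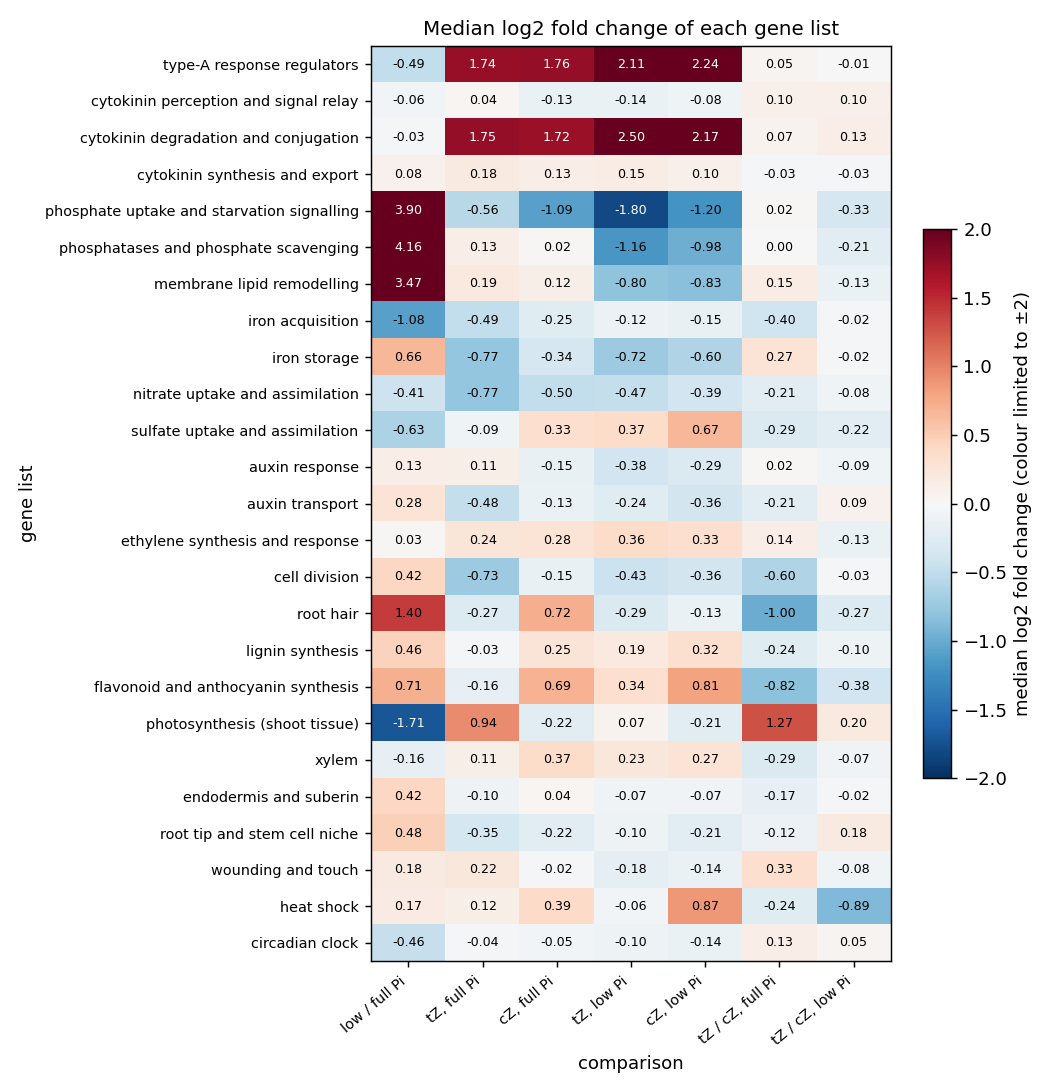
Median log2 fold change (colour, limited to ±2) of each of 25 gene lists in the 7 pairwise comparisons; rows are lists and columns comparisons. The phosphate lists are positive under starvation (phosphatases 4.16) and negative with either zeatin in low phosphate (-1.16 and -0.98), while type-A response regulators are positive in all 4 zeatin comparisons.

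The response to the isomers is shared to a large part. In full phosphate 3417 genes changed the same way with both (1537 up, 1880 down) and 362 in opposite ways. In low phosphate 4572 changed the same way (1904 up, 2668 down) and 4 in opposite ways. Independent lists would share 1295 and 1028. The correlation of the fold changes is 0.72 in full and 0.90 in low phosphate, and simulated data with only the shared controls in common gave 0.49 and 0.50 and no shared calls. The covariance is 0.338 and 0.386, against 0.018 and 0.017 in the simulated data. Starvation and zeatin pull apart for many genes that starvation raised: of these 4569, trans-zeatin in low phosphate lowered 1682 (36.8%) and cis-zeatin 1368 (29.9%), while 457 and 553 rose further. Of 4356 genes that starvation lowered, 948 (21.8%) rose with trans-zeatin and 675 (15.5%) fell further. With cis-zeatin 763 (17.5%) of them rose and 833 (19.1%) fell further, where independent lists would give 789 falling further. Among all tested genes cis-zeatin in low phosphate also lowered more (3620) than it raised (2613). Opposite changes sum to 2630 with trans-zeatin and 2131 with cis-zeatin, where independent lists would give 1443 and 1397 and simulated data with only the shared controls gave at most 1. Changes in the same direction as starvation numbered 1132 and 1386, against 1433 and 1387 for independent lists. The untreated low-phosphate libraries serve in both comparisons, and with 3 of them they cannot be divided. The simulated data hold the starvation effect but no zeatin effect, so hardly any zeatin calls could arise in them. The independent lists hold no shared controls. Part of the excess over independent lists can therefore still come from the shared controls, and the same holds for genes shared by the isomers. At a 2-fold threshold the shared counts are 911 in full and 1151 in low phosphate, and the opposite counts 376 for trans-zeatin and 291 for cis-zeatin.

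trans-Zeatin against cis-zeatin in full phosphate, at 5 µM and 8 h each, asks whether the isomers differ in fed roots. The type-A response regulators hardly do: only ARR5 (0.29, 95% interval 0.08 to 0.51) and ARR9 (0.26, 95% interval 0.10 to 0.43) were higher with trans-zeatin, while ARR4 (AT1G10470) (-0.09, 95% interval -0.24 to 0.07), ARR7 (-0.13, 95% interval -0.32 to 0.06) and ARR15 (-0.05, 95% interval -0.34 to 0.25) gave no call. With quantile normalization neither ARR5 nor ARR9 is called, and the ARR5 call also ends when certain single libraries are left out. CKX5 was lower (-0.41, 95% interval -0.55 to -0.26) and UGT85A1 (AT1G22400), a cytokinin glucosyltransferase gene, higher with trans-zeatin (0.60, 95% interval 0.32 to 0.87). Cell-division genes were lower in 21 of 24 cases (median -0.60, adjusted p = 0.545 with an estimated correlation), as in TSO2 (AT3G27060) (-0.92 ± 0.10) and PCNA1 (AT1G07370) (-1.01 ± 0.13). Root-hair genes were lower in 13 of 17 (adjusted p = 0.545 with an estimated correlation), as in the expansin gene EXPA7 (AT1G12560) (-1.03 ± 0.13) and RHS19 (-1.20 ± 0.17). Flavonoid genes were lower in 7 of 9 cases (adjusted p = 0.545 with an estimated correlation; FLS1 (AT5G08640) -0.82 ± 0.12). Iron acquisition was lower in 11 of 22 (adjusted p = 0.545 with an estimated correlation; NAS1 -1.73 ± 0.14, IRT1 -1.71 ± 0.23) and lignin in 10 of 15 (adjusted p = 0.748 with an estimated correlation; PAL2 (AT3G53260) -0.49 ± 0.09). NRT2.1 (-2.78 ± 0.29) and NRT1.1 (-2.31 ± 0.14) were lower, and the nitrate list is not past the test (adjusted p = 0.155).

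Higher with trans-zeatin were SEN1 (4.21 ± 0.22), AT1G19530 (3.78 ± 0.24), BCAT-2 (AT1G10070) (3.38 ± 0.15) and DIN2 (AT3G60140) (2.93 ± 0.34). SEN1 and DIN2 are known as genes induced in the dark, and BCAT-2 encodes a branched-chain amino acid transaminase. Lower were AT4G01390 (-2.96 ± 0.22), ATC (AT2G27550) (-2.95 ± 0.18) and the aspartate kinase gene AK3 (AT3G02020) (-2.38 ± 0.21). Phosphate uptake genes split, 4 up and 3 down of 19, and PHO1;H1 was lower (-1.18 ± 0.17). Photosynthesis genes were higher in 13 of 16 cases (median 1.27, adjusted p = 0.545 with an estimated correlation; LHCA4 2.01 ± 0.14), wounding genes in 7 of 16 (adjusted p = 0.114; ERF104 (AT5G61600) 1.08 ± 0.08). With edgeR, 4137 genes were higher and 4095 lower, 1004 at least 2-fold, and the isomers were not sequenced in the same set.

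**Figure D5:**
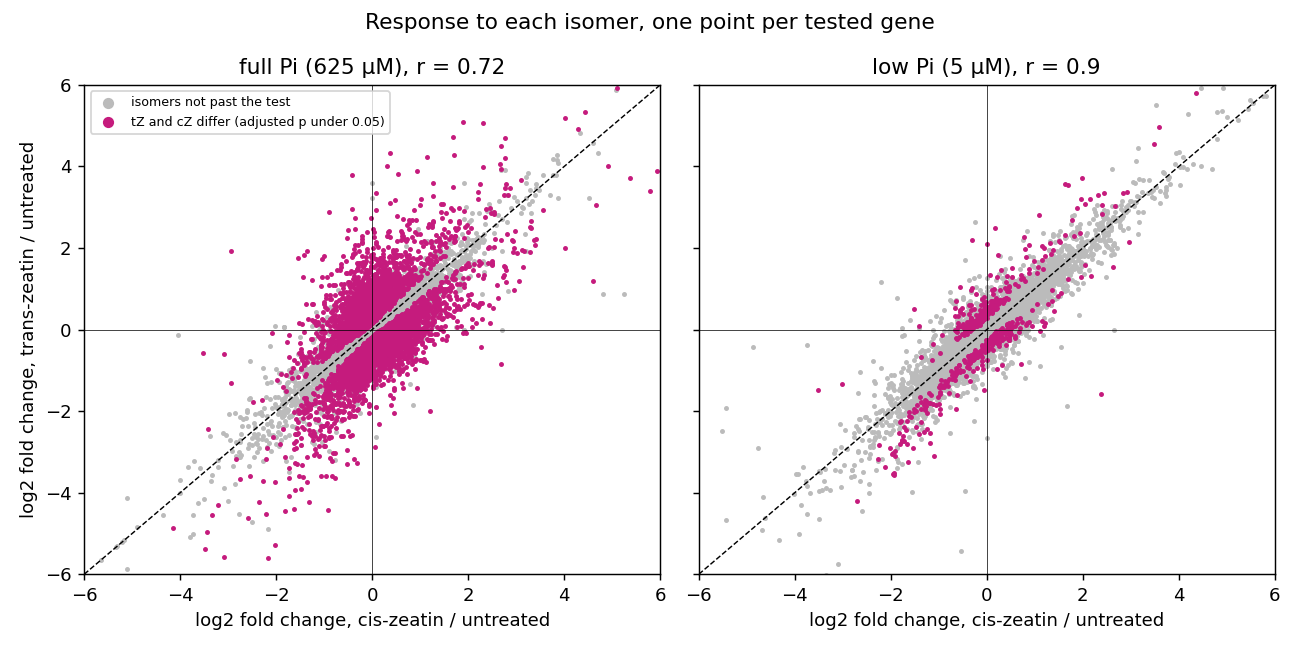
log2 fold change with trans-zeatin (vertical) against that with cis-zeatin (horizontal), each against untreated roots, in full (left) and low (right) phosphate; each point is a tested gene, coloured where the isomers differ, and 30 genes outside ±6 are not drawn. The points lie closer to the diagonal in low phosphate (r = 0.90) than in full phosphate (0.72).

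In low phosphate few genes were called for a difference between the isomers, and no type-A response regulator was among them. ARR5 (0.01, 95% interval -0.20 to 0.23), ARR7 (-0.01, 95% interval -0.21 to 0.18), ARR4 (-0.06, 95% interval -0.21 to 0.10), ARR15 (0.18, 95% interval -0.08 to 0.45) and ARR6 (-0.13, 95% interval -0.30 to 0.03) gave no call. The widest interval among all 10 is that of ARR17 (-0.21, 95% interval -0.69 to 0.27), and no other reaches beyond 0.45 in either direction. No degradation gene was called either, with UGT85A1 closest (0.32, 95% interval 0.06 to 0.59, adjusted p = 0.17). Of the cytokinin synthesis genes LOG3 (AT2G37210) was higher (0.83 ± 0.18) and IPT5 lower (-0.91 ± 0.24) with trans-zeatin, though both calls end when only these groups are used or without trans-zeatin replicate 2, and that for IPT5 also without other single libraries. Phosphate genes were somewhat lower with trans-zeatin: PHT1;4 (-0.56, 95% interval -0.74 to -0.38), SPX3 (-0.89, 95% interval -1.19 to -0.59), SPX1 (-0.68, 95% interval -0.93 to -0.44), PS2 (95% interval -1.26 to -0.74) and PECP1 (-1.07, 95% interval -1.46 to -0.68). Of the uptake list 6 of 19 genes were lower (10 adjusted over the list alone, adjusted p = 0.0791 with an estimated correlation) and of the phosphatases 4 of 14 (adjusted p = 0.0791 with an estimated correlation). GDPD1, of lipid remodelling, was lower as well (-0.58, 95% interval -0.81 to -0.36). When only these 6 libraries are used the calls for PHT1;4, SPX1 and GDPD1 end, and with limma those for SPX3 and PECP1 do, while PS2 keeps its call.

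Higher with trans-zeatin were BCAT-2 (95% interval 1.90 to 3.11), AT1G19530 (2.08 ± 0.27), SEN1 (1.61 ± 0.28) and ASN1 (AT3G47340) (1.74 ± 0.22), an asparagine synthetase gene known to be induced in the dark. CYP83A1 (AT4G13770) (-1.63 ± 0.15) and BCAT4 (AT3G19710) (-1.59 ± 0.19), of methionine-derived glucosinolate synthesis, and AK3 (-1.50 ± 0.18) were lower. Flavonoid genes had 1 of 9 past the test over all genes and 6 over the list alone (adjusted p = 0.255 with an estimated correlation), and cell-division genes none (median -0.03, adjusted p = 0.258). Heat-shock genes were lower in 3 of 5 cases (median -0.89, adjusted p = 0.255 with an estimated correlation), a larger shift than any phosphate list shows here. All 3 heat-shock calls end when only these groups are used. With edgeR, 270 genes were higher and 283 lower, 67 at least 2-fold. Before adjustment 3892 of 19982 genes had an edgeR p under 0.05, against 9717 in full phosphate. Genes without a call can therefore still differ by small amounts. The 553 called genes become 79 with only these groups and 926 with DESeq2. Leaving out a single library gives 293 (trans-zeatin replicate 2), 364 (cis-zeatin replicate 2) or 847 (cis-zeatin replicate 1), and 325 are called without both replicates 2.

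The interaction of trans-zeatin with phosphate asks whether the response to that isomer depends on phosphate. Lipid remodelling genes responded more negatively in low phosphate in 13 of 15 cases (median -1.34, adjusted p = 0.00207 with an estimated correlation), as in SQD1 (-1.90 ± 0.11) and GDPD1 (-2.50 ± 0.16). Phosphatases did so in 9 of 14 (median -1.54, adjusted p = 0.00775 with an estimated correlation; PAP17 -2.23 ± 0.18, PS2 -2.75 ± 0.27). Starvation had raised most genes of both lists, so untreated levels were lower in full phosphate, as for NPC4 (10.2 against 199 CPM). These interactions therefore hold the response from a low starting level in full phosphate as well as the fall in low phosphate. Phosphate uptake had 9 more negative and 2 more positive of 19 (adjusted p = 0.389 with an estimated correlation), with SPX2 (AT2G26660) at -1.14 ± 0.11 and PHO1;H1 at 2.48 ± 0.20. Among cytokinin genes ARR7 (1.28 ± 0.14), ARR6 (0.61 ± 0.12), CKX4 (1.60 ± 0.16) and CYP735A2 (1.85 ± 0.16) had a larger log2 rise in low phosphate. Untreated levels of all of them were lower there than in full phosphate: ARR7 8.98 against 24.6 CPM, ARR6 26.4 against 43.9, CKX4 6.75 against 43.7 and CYP735A2 22.1 against 58.6. A larger log2 rise therefore need not mean a higher level with trans-zeatin. The log2 rise of ARR17 (-1.95 ± 0.58), ARR16 (-1.03 ± 0.27) and CKX3 (-0.67 ± 0.22) was smaller, while ARR5 (0.29, 95% interval -0.04 to 0.61) and ARR9 (-0.02, 95% interval -0.25 to 0.21) gave no call. Of the type-A response regulators 3 were more positive and 2 more negative of 10, and the list is not past the test (adjusted p = 0.0994). LOG1 was more negative in low phosphate (-1.23 ± 0.20). Without replicate 2 of the untreated full-phosphate group the calls for ARR16, ARR17 and CKX3 end, and those for ARR17 and CKX3 also end without certain other single libraries or with the sequencing set as a term. Cell-division genes were more positive in 10 of 24 cases (adjusted p = 0.389 with an estimated correlation; TSO2 0.88 ± 0.14) and nitrate genes in 10 of 20 (adjusted p = 0.389 with an estimated correlation; NRT2.1 3.16 ± 0.36). Auxin response genes were more negative in 7 of 24 (adjusted p = 0.339 with an estimated correlation; GH3.3 (AT2G23170) -2.47 ± 0.31). Photosynthesis genes had 4 of 16 more negative (adjusted p = 0.516 with an estimated correlation; LHCA4 -1.20 ± 0.22) and wounding genes 7 of 16 (adjusted p = 0.389 with an estimated correlation). With edgeR, 1854 genes were more positive and 2231 more negative, 723 at least 2-fold, and the sequencing set as a term gives 1767 in place of 4085.

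For cis-zeatin the interaction with phosphate covers fewer genes. Lipid remodelling was again more negative in 12 of 15 cases (median -0.99, adjusted p = 0.000645 with an estimated correlation; NPC4 -2.15 ± 0.16, SQD2 -1.64 ± 0.13) and phosphatases in 7 of 14 (median -0.96, adjusted p = 0.0179 with an estimated correlation; PAP17 -1.44 ± 0.19). The lipid genes called with cis-zeatin in full phosphate all rose: GDPD3 (AT5G43300) (2.29 ± 0.32), NPC4 (0.84 ± 0.12) and PAH1 (AT3G09560) (0.29 ± 0.09). For such genes the interaction holds a rise in full phosphate and not only a fall in low phosphate. The uptake list is not past the test (adjusted p = 0.183), with SPX1 at -1.01 ± 0.19 and PHT1;4 at 0.93 ± 0.13. ARR7 (1.16 ± 0.14), ARR6 (0.63 ± 0.12), CKX4 (1.55 ± 0.16), CYP735A2 (1.60 ± 0.16) and IPT3 (1.71 ± 0.18) were more positive in low phosphate, and 5 of 10 type-A response regulators were (adjusted p = 0.345 with an estimated correlation). Mean levels with cis-zeatin were still lower in low than in full phosphate for ARR7 (67.4 against 82.7 CPM), ARR6 (110 against 118) and CKX4 (72.2 against 159). They were higher for CYP735A2 (286 against 250) and IPT3 (6.79 against 4.67). APR2 (AT1G62180) (0.80 ± 0.12) and BT1 (1.58 ± 0.16) were more positive, RHS19 more negative (-1.20 ± 0.24). No photosynthesis, lignin or heat-shock gene was past the test. With edgeR, 315 genes were more positive and 527 more negative, 252 at least 2-fold.

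The isomer-by-phosphate interaction asks whether the difference between the isomers depends on phosphate. For type-A response regulators it did only for ARR9 (-0.41, 95% interval -0.64 to -0.18), while ARR7 (0.12, 95% interval -0.16 to 0.39) and ARR5 (-0.28, 95% interval -0.58 to 0.03) gave no call. Cell-division genes were more positive in low phosphate in 15 of 24 cases (median 0.55, adjusted p = 0.637 with an estimated correlation), as in CDT1A (AT2G31270) (0.90 ± 0.15), TSO2 (0.83 ± 0.14) and MCM2 (AT1G44900) (0.83 ± 0.15). Many genes of this list were lower with trans-zeatin than with cis-zeatin in full phosphate, and none was called so in low phosphate. Against untreated roots both isomers lowered many of them in low phosphate. Root-hair genes followed in 7 of 17 cases (adjusted p = 0.637 with an estimated correlation; EXPA7 0.69 ± 0.18) and auxin transport in 7 of 12 (adjusted p = 0.637 with an estimated correlation; AUX1 (AT2G38120) 0.41 ± 0.11). NRT2.1 (2.82 ± 0.37), NRT1.1 (2.12 ± 0.19), KIN1 (AT5G15960) (2.34 ± 0.25) and FRO2 (2.43 ± 0.34) were more positive, DIN2 (-2.63 ± 0.45) and GDPD2 (AT5G41080) (-1.01 ± 0.11) more negative. With trans- and cis-zeatin in low phosphate NRT2.1 had 57.6 and 55.9 CPM, NRT1.1 159 and 181 and KIN1 63.2 and 49.1. FRO2 had only 2.06 and 1.44 CPM there. A more positive interaction therefore need not mean a higher level with trans-zeatin in low phosphate. Photosynthesis genes were more negative in 4 of 16 cases (adjusted p = 0.637 with an estimated correlation; LHCA4 -1.30 ± 0.23) and wounding genes in 5 of 16 (adjusted p = 0.637 with an estimated correlation; ERF104 -0.94 ± 0.11). With edgeR, 1720 genes were more positive and 1946 more negative, 500 at least 2-fold.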

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

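A rule set before the data were examined takes every result that tests whether a response differs between groups. It takes all 3 interactions by definition, whatever their counts. They are the trans-zeatin interaction with phosphate (4085 genes), the cis-zeatin interaction (842) and the isomer-by-phosphate interaction (3666). Being listed here is therefore no evidence for them.

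These tests were chosen only after the result was seen: the sequencing-set test for the isomer difference, the length and shoot-tissue tests for the library that lies apart, and the shoot-tissue and sequencing-set tests for photosynthesis genes. In the tests of explanations below, ± comes from resampling genes unless stated otherwise. It therefore does not measure the spread between libraries.

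An isomer difference was called for 8232 genes in full and 553 in low phosphate. A difference between sequencing sets could make this, but the slope of the trans-zeatin response, measured within a single set, on the isomer difference is 0.89 ± 0.018. Both contain the full-phosphate trans-zeatin libraries, which alone pushes the slope up, but with the response taken from 1 of these libraries and the difference from the others it is 0.81 ± 0.016, 0.81 ± 0.02 and 0.67 ± 0.018, which argues against the set as the whole cause. The slope test was chosen after another test of the same explanation had been seen, the slope of the cis-zeatin interaction (0.14 ± 0.012), and a part played by the set stays open since the starvation response has a slope of -0.43. Larger spread among low-phosphate zeatin libraries would hide differences, but the noise-corrected spread of the isomer fold changes is itself smaller there (ratio 0.42 ± 0.016, 0.207 against 0.488). With the length and GC trend removed 8939 genes are called in full and 561 in low phosphate, which argues against that trend.

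Replicate 2 of low-phosphate cis-zeatin lies about as far from its replicates as from the trans-zeatin group (0.353 against 0.385, ratio 0.92), and its deviation follows gene length (r = -0.62). No library of another group goes beyond 0.28 in size. The other 2 of its own group reach 0.47 and 0.44, but each is measured against a mean that includes replicate 2, so these values partly mirror it. Replicate 2 also has the lowest GC content (44.24%) and the highest counted share of clean reads (91.02%) of all libraries. The test set it against all other libraries, its own replicates included, so whether a length trend sets it apart stays open. Shoot tissue stays open too: the summed photosynthesis signal is 1.1 ± 0.05 (counting error only) times that of its replicates, but the same ratio spans 0.68 to 1.67 in the libraries of other groups. The bounds of that test were set after the sums per library had been seen, and the first test, the median deviation of the photosynthesis list (0.07 ± 0.149), had left it undecided as well. A swapped label is undecided: on the axis from cis-zeatin (0) to trans-zeatin (1) over 325 genes the library sits at 0.3 ± 0.032, short of the 0.75 that a swap needs but above the bound of 0.25 set beforehand, and trans-zeatin replicate 2 sits at 0.84 ± 0.027.

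Photosynthesis genes are higher with trans-zeatin than with cis-zeatin in full phosphate (median 1.27). Shoot tissue carried along could raise them, and this stays open. The median gain of the other single-copy genes is 0.08 ± 0.034 of the gain of LHCA4 (19.6 to 68.3 CPM), but in untreated roots these genes already have a median of 0.17 of its level, so the gain does not decide. Among them LHCB4.1 (AT5G01530) goes from 13.5 to 35.9 CPM and LHCB6 (AT1G15820) from 2.59 to 2.38. A difference between sequencing sets is argued against by a median of 0.94 within a single set.

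Regrouping the 6 libraries of a pairwise comparison gives 10 splits, too few for a share under 0.05. In each of the 7 pairwise comparisons the real grouping is 1 of 1 split with that many genes. The highest other count is 0 for starvation (8925 real), trans-zeatin in full phosphate (9875), cis-zeatin in full (5237) and low phosphate (6233) and the isomers in full (8232) and low phosphate (553), and 1 for trans-zeatin in low phosphate (6440). Every other split mixes the compared groups, which adds their difference to the spread within groups. Low counts from such splits therefore do not measure chance.

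For the interactions 100 splits within the phosphate levels were drawn, the real one included. As many genes came from 6 splits for trans-zeatin (real 4085, highest other 7273), 10 for cis-zeatin (842, highest other 3207) and 11 for the isomers (3666, highest other 6358). Every other split with as many genes kept the real labels at 1 phosphate level, so its interaction holds the treatment effect of that level and does not measure chance. The 81 splits that mixed both levels called 0 genes with edgeR, but mixing adds the treatment effect to the spread within groups. These splits therefore do not decide whether chance can be excluded for the 3 counts.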

How the results depend on the processing

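The counts past the threshold with edgeR are 8925 (starvation), 9875 and 5237 (trans- and cis-zeatin, full phosphate), 6440 and 6233 (low phosphate), 8232 and 553 (isomers, full and low phosphate), and 4085, 842 and 3666 (interactions with trans-zeatin, cis-zeatin and isomer). A 2-fold threshold makes them 1764, 2078, 1328, 1518, 1374, 1004, 67, 723, 252 and 500. Genes shared by the isomers become 911 in full and 1151 in low phosphate, and genes changed by starvation and zeatin 376 opposite and 122 the same way with trans-zeatin, 291 and 141 with cis-zeatin. With an estimated correlation the lists past the test number 5, 2, 2, 5, 5, 0, 0, 2, 2 and 0, against 11, 7, 9, 9, 14, 6, 10, 11, 8 and 9 with the preset one. The sequencing set as a term gives 4140 for trans-zeatin and 2678 for cis-zeatin in low phosphate (share up 55 against 41.9%) and 1767 for the trans-zeatin interaction; the cause was not tested. For the isomers in low phosphate only the compared groups give 79, DESeq2 gives 926 (the cause was not tested) and leaving out both replicates 2 gives 325. Leaving out a single library gives 7511 to 8307 (starvation), 8507 to 9021, 4284 to 4633, 5336 to 6057, 5226 to 6260, 6687 to 7359, 293 to 847 (isomers, low phosphate), 3059 to 4517, 572 to 973 and 2652 to 3972, in the same order. Only the isomers in low phosphate move by more than 1.5 times: 293 without trans-zeatin replicate 2, 364 without cis-zeatin replicate 2 and 847 without cis-zeatin replicate 1. A replicate block for pairing moves no count that far, and with it 1 list is lost for starvation and 1 for cis-zeatin in low phosphate. Of 17292 values of named genes under other settings 16606 keep their call, 593 lose it and 44 gain it, and no called gene changes sign. Other pseudocounts and recovered reads were not run, as the values are raw counts.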

Other observations

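Several genes and lists were not described above. Sulfate genes in full phosphate had 5 up and 5 down of 15 with trans-zeatin (adjusted p = 0.682) and 8 up and 4 down with cis-zeatin (adjusted p = 0.272), where GGCT2;1 (AT5G26220) (1.62 ± 0.26) and SULTR1;1 (AT4G08620) (0.92 ± 0.16) rose and SULTR2;1 (AT5G10180) (-0.87 ± 0.13) fell. The same GGCT2;1, for a glutathione-degrading enzyme, rose in low phosphate by 3.16 ± 0.28 with trans-zeatin and 2.98 ± 0.28 with cis-zeatin. The iron transporter gene IRT2 (AT4G19680) rose with cis-zeatin in full phosphate (2.69 ± 0.18) and with either isomer in low phosphate (2.52 ± 0.17 and 2.60 ± 0.17), while FIT fell in all 3 (-1.37 ± 0.08, -1.25 ± 0.08 and -1.19 ± 0.08). The type-B response regulator gene ARR11 (AT1G67710) fell in low phosphate with trans-zeatin (-1.62 ± 0.13) and cis-zeatin (-1.67 ± 0.13), and the coumarin synthesis gene F6'H1 (AT3G13610) rose (0.92 ± 0.09 and 1.13 ± 0.09).

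Tissue lists moved little with zeatin in low phosphate. SCR (AT3G54220), a gene of endodermis identity, fell with trans-zeatin (-0.58 ± 0.12) and cis-zeatin (-0.60 ± 0.12), and the suberin gene CYP86A1 (AT5G58860) rose with trans-zeatin (0.72 ± 0.12) and cis-zeatin (0.70 ± 0.12). No gene of the root-tip list differed between the isomers in low phosphate (median 0.18, adjusted p = 0.567), and none of the endodermis list did (median -0.02, adjusted p = 0.622).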
